A study of Mus musculus with 12 samples.

How the data were processed

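Expression was measured in GLAST-selected white matter astrocytes from wild-type mice after 0, 3 and 12 weeks of 0.2% (w/w) cuprizone and from GnT-IX-deficient mice after 12 weeks, with 3 arrays in each of the 4 groups. Per the labels' protocols, white matter was dissociated with papain, Fc receptors were blocked, and cells were selected with anti-GLAST microbeads. Total RNA was extracted with 1 of a pair of kits, miRNeasy or NucleoSpin RNA XS, and labelled with a 3' IVT Pico kit. Which sample went with which kit is not given in the sources used here, so kit and group could not be separated. Per the submitters' processing notes, the authors processed the arrays in Affymetrix Expression Console 1.4 with RMA (background correction, quantile normalization and summary of the probes of each transcript cluster), and the deposited values are on the log2 scale. RMA sets the arrays to a like distribution and compresses the fold changes of dim transcripts. No genome build is named in the sources used here, so no coordinates are printed.

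The table held 22206 transcript clusters in 12 columns, with values from 1.43 to 12.5. Columns were matched to samples by their labels, and groups and replicate numbers came from the sample titles. No columns of a group were identical. Clusters were named through the platform's annotation and the RefSeq table of GRCm38.p6, by Entrez identifier: 19572 clusters had 1 symbol and all matched, none had several, and 2634 clusters are unnamed here and were left out of the gene tests. For 55 genes with several clusters, the one with the highest mean over the 12 arrays was used. Of those called, none had clusters of opposite sign. This left 19505 genes, with no filter on dim genes. No detection calls were used here, so a lower quartile of 3.73 to 3.85 per array served only to mark dim genes.

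Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 1 mean per group, all 12 arrays in one fit and 8 residual degrees of freedom, and Benjamini-Hochberg adjustment over genes at a threshold of 0.05. Errors of log2 differences are standard errors from that fit, and means are given with the SD over 3 arrays. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 35 lists within a comparison, and again with an estimated correlation. The lists, 20 of pathways or cell states and 15 of cell type markers, held 524 genes, of which 473 were measured here. The sets of genes called at 3 weeks were tested the same way, adjusted over the pair of sets. Members were also counted with their p-values adjusted over the list alone.

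The genes named in the text followed a rule. Mgat5b, Slc1a3 and Gfap were always taken, then up to 10 rises and 10 falls per comparison among genes past the threshold whose 3 values in one group all lay beyond the 3 in the other, and up to 4 members past the threshold per list. Where fewer than 10 genes passed, the 10 with the smallest p were added. The groups, tests, lists, naming rule and all alternatives but the choroid plexus and ependymal covariates were fixed before the data were examined.

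The gene test was tried on simulated data made from the real means and spreads, with each gene drawn independently. Correlation between genes was thus left out, so recovery in the real data may differ. With a log2 change of 1 the gene test recovered 62.7% of changed genes for 3 against 0 weeks, 71.6% for 12 against 0 weeks, 50.7% for 12 against 3 weeks and 55.2% for the genotypes, and with a log2 change of 2 it recovered 93.9%, 92.4%, 93.9% and 97.0%. False calls numbered 8 of 171, 7 of 181, 9 of 167 and 12 of 170 simulated calls in the 4 comparisons. Groups of 3 arrays did not overlap for 21.2%, 20.8%, 15.9% and 10.8% of genes in the 4 comparisons, where chance gives 10%. The alternatives covered a second normalization, centring, a filter on dim genes, the choice of clusters, the variance model, array weights, the arrays in the fit, the replicate number as a block, marker means of other cells as covariates, a minimum fold, and leaving out each array. Figures were drawn with matplotlib 3.10.9.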

Results

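The series asked how white matter astrocytes change while mice are fed cuprizone, a copper chelator that kills oligodendrocytes and strips myelin, and what the loss of the glycosyltransferase GnT-IX does to these cells. Astrocytes were taken from dissociated white matter with beads against GLAST, the glutamate transporter encoded by Slc1a3. Wild-type C57BL/6 mice were sampled after 0, 3 and 12 weeks of a 0.2% cuprizone diet that began at 8 to 12 weeks of age, and GnT-IX-deficient mice after 12 weeks. The range of starting ages was the same in every group, so weeks of diet went with age at sampling. No untreated group kept for 3 or 12 weeks was analysed here, so effects of cuprizone and of age could not be told apart in wild-type mice. Each of the 4 groups held 3 biological replicates, with 1 array each, 12 arrays in all. Array medians lay between 5.38 and 5.45 on the log2 scale, and arrays of one group correlated with r of 0.974 to 0.985 across genes. The number of arrays limits the precision of every value.

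Mature oligodendrocyte markers lay well above the array medians in every group, with group means of 8.91 to 9.62. At 0 weeks the homeostatic astrocyte list (transporters, gap junction proteins and other genes of resting astrocytes) averaged 9.81 ± 0.18 (log2, SD, n = 3) and the mature oligodendrocyte markers 9.62 ± 0.18 (SD, n = 3). Microglia and macrophage markers averaged 5.39 ± 0.29 (SD, n = 3) at 0 weeks and 8.32 ± 0.58 (SD, n = 3) at 12 weeks. The 0-week value lay near the array medians, and signal over background was not measured, so it does not show microglial transcripts at that time. After 3 weeks the arrays were unequal, with microglial means of 8.82 in replicate 1, 6.97 in replicate 2 and 6.52 in replicate 3. Choroid plexus markers lay between 4.80 and 6.81 in the 9 wild-type arrays and reached 9.66, 8.52 and 6.33 in the 3 GnT-IX-deficient arrays.

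**Figure D1:**
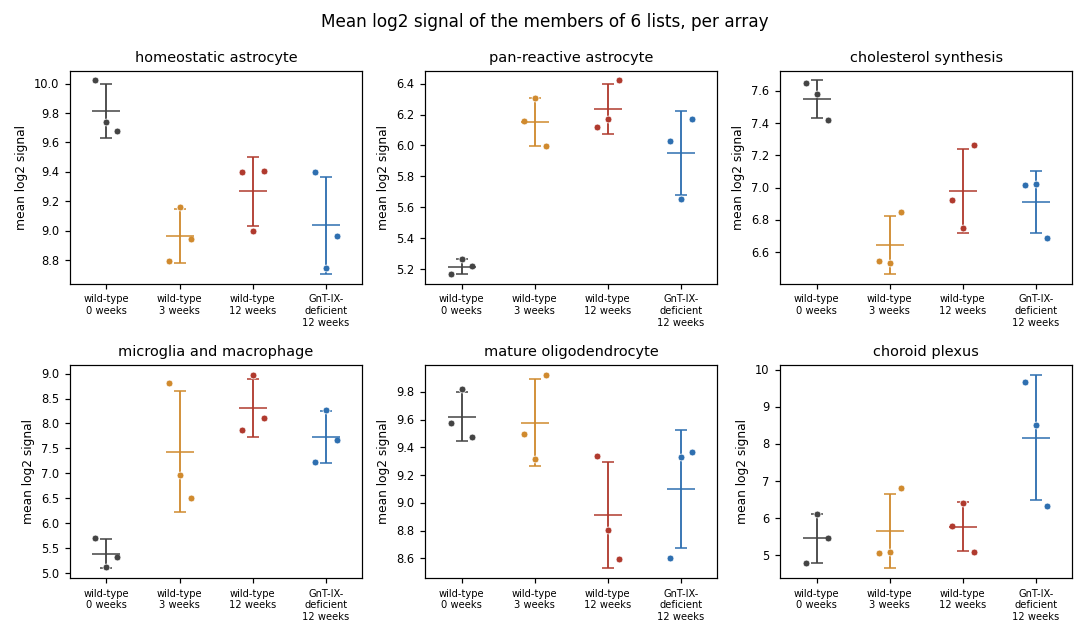
Mean log2 signal of the measured members of 6 lists (y axis) in each array (points) by group (x axis), with the group mean and SD as a bar. Homeostatic astrocyte and cholesterol synthesis means were lower after 3 weeks than at 0 weeks, microglial means were higher, and choroid plexus means reached 9.66 in a GnT-IX-deficient array.

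The first comparison asked what 3 weeks of cuprizone did to wild-type cells. Some reactive astrocyte and stress response genes rose, and some genes of resting astrocytes and of sterol synthesis fell, although no list call held with an estimated correlation. Serpina3n, a serine protease inhibitor of reactive astrocytes, rose by 2.95 (SE 0.35, adjusted p = 0.000942), and Gfap, the astrocyte intermediate filament, rose by 1.97 (SE 0.46, adjusted p = 0.0305). Asns, the asparagine synthetase gene, rose by 2.25, and Ddit3, which encodes the stress transcription factor CHOP, by 2.23. Slc1a3, the antigen of the isolation, fell by 1.35 from 8.35 ± 0.44 (SD, n = 3, adjusted p = 0.0150). Slc1a3 missed the threshold without replicate 1 of the 0-week group (adjusted p = 0.0839) or replicate 3 of the 3-week group (0.0569), and Gfap without replicate 1, 2 or 3 of the 0-week group (0.0734, 0.0976 and 0.0986) or replicate 1 or 2 of the 3-week group (0.0638 and 0.0909). Over all alternatives the adjusted p of Slc1a3 ranged from 0.00406 to 0.425 and that of Gfap from 0.00955 to 0.339. In all, limma called 632 of 19505 genes, 315 higher and 317 lower, and 367 of them changed at least 2-fold.

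Among the genes with the largest rises at 3 weeks were Cdkn1a (3.28), which encodes the cell cycle inhibitor p21, and Syt4 (3.19, adjusted p = 3.95e-05), a synaptotagmin of vesicle traffic. The others were genes of myeloid cells: Mmp12 (3.66), the macrophage elastase, the chemokine gene Ccl3 (3.50), Mpeg1 (3.47), Ly86 (3.27), the complement receptor gene C3ar1 (3.23), and the Bcl-2 family genes Bcl2a1a (3.75), Bcl2a1b (3.70) and Bcl2a1d (3.29). The Bcl2a1 genes are near-identical copies that probes may not separate, so the value of each is uncertain. Mmp12, Ccl3 and Mpeg1 averaged below the lower quartile of the arrays at 0 weeks, so the sizes of their rises are uncertain too. Cdkn1a was at 9.02, 9.29 and 6.54 in the 0-week arrays, so replicate 3 of that group enlarged its rise. Its call was kept in all alternatives but the covariates. The largest falls were in Fzd2, a Wnt receptor gene (-2.21), Gdf10 (-2.19), Kirrel2 (-2.12), Rpe65 (-1.93), the potassium channel gene Kcnk1 (-1.91), the sterol methyl oxidase gene Msmo1 (-1.91), Lama3 (-1.88), Nat8f5 (-1.85), Chrdl1 (-1.84) and Scara3 (-1.83).

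Of 18 measured homeostatic astrocyte genes, 8 fell at 3 weeks and none rose (14 changed when adjusted over the list alone), with a median of -0.91. They included Gja1 (-1.30) and Gjb6 (-1.29), the main astrocyte connexin genes, and Ntsr2 (-1.33). Of 9 grey matter astrocyte genes, 5 fell (7 adjusted over the list alone), among them the amino acid transporter gene Slc7a10 (-1.58), the phagocytosis bridge gene Mfge8 (-1.53) and Chrdl1. Camera called both lists lower, with adjusted p = 8.91e-14 and 8.36e-10, but adjusted p = 0.153 and 0.114 with an estimated correlation. Cholesterol synthesis genes moved together: 11 of 19 fell and none rose (15 adjusted over the list alone), with a median of -0.89. Besides Msmo1 these were led by Mvd (-1.55), Fdft1 (-1.50), the squalene synthase gene, and Nsdhl (-1.34). The list had an adjusted p of 6.89e-17, and adjusted p = 0.114 with an estimated correlation.

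Of 25 integrated stress response genes, 11 rose and 1 fell at 3 weeks (15 adjusted over the list alone), with a median of 0.69. Besides Asns and Ddit3, Nupr1 rose by 1.71 and the mitochondrial folate enzyme gene Mthfd2 by 1.47, while Cth, picked after its value was seen, fell by 1.02. Camera gave adjusted p = 5.64e-08, and adjusted p = 0.114 with an estimated correlation. Pan-reactive astrocyte genes had a median of 0.63, with 3 of 13 past the threshold (7 adjusted over the list alone), which were Serpina3n, Gfap and Cd44 (1.99). That list had adjusted p = 2.41e-07, and adjusted p = 0.0598 with an estimated correlation. Of 19 immediate early and dissociation genes, 4 rose and 1 fell (11 adjusted over the list alone), the rises being Egr2 (2.19), Junb (1.71), Egr1 (1.64) and Fosb (1.27). This list had adjusted p = 2.71e-07, and adjusted p = 0.153 with an estimated correlation. Type I interferon genes had 2 of 20 members past the threshold (10 adjusted over the list alone), Usp18 (1.71) and Ifit1, with adjusted p = 1.82e-07, and adjusted p = 0.153 with an estimated correlation.

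Microglial markers rose with these changes: 10 of 15 passed the threshold (12 adjusted over the list alone), with a median of 2.28, and those that passed included Tyrobp (3.09), C1qa (2.74), Laptm5 (2.54) and Trem2 (2.42). Their list had adjusted p = 5.54e-16, and adjusted p = 0.153 with an estimated correlation. Of 10 neuron markers, Gad1 (1.73), which makes GABA, and Snap25, a synaptic gene, rose beside Syt4 (2 adjusted over the list alone), with a list median of 0.25, adjusted p = 0.0231, and adjusted p = 0.507 with an estimated correlation. Phagocytosis genes went both ways, Elmo1 rising by 1.11 while Mfge8, the receptor gene Mertk (-1.39) and Gulp1 (-1.10) fell, and that list was not called (adjusted p = 0.396). Matrix genes also went both ways, Cd44 rising and the link protein gene Hapln1 (-1.73), Gpc6 (-0.99) and Cspg5 (-0.58) falling, with adjusted p = 0.825 for the list, whose median was 0.33 although the test leaned lower. Camera called 17 of the 35 lists at 3 weeks, 14 higher and 3 lower, and none held with an estimated correlation. With the microglial marker mean of each array as a covariate, 5 genes passed, all higher: Syt4 and, named here after their values were seen, Eda2r, Nrsn2, Slc32a1 and Usp29. The 632 called genes retained a median of 81.3% of their log2 fold change with this covariate while the SE grew 1.58 times (median over all genes). The microglial median went from 2.28 to 0.21, but the covariate is the mean of those same markers, so a value near 0 was built in. The median of homeostatic astrocyte genes went from -0.91 to -0.56 and that of cholesterol synthesis genes from -0.89 to -0.73. For integrated stress response genes it went from 0.69 to 0.51, for immediate early genes from 0.53 to 0.23 and for pan-reactive genes from 0.63 to 0.81. Ntsr2 was then at -0.67 (SE 0.37), Gjb6 at -0.68 (SE 0.40) and Gja1 at -0.86 (SE 0.34), while Serpina3n was at 3.20 (SE 0.54) and Asns at 2.20 (SE 0.44). The count was 192, 244 or 360 without replicate 1, 2 or 3 of the 0-week group, and 270 or 385 without replicate 1 or 3 of the 3-week group.

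The second comparison set wild-type cells after 12 weeks of cuprizone against 0 weeks. Genes of microglia and macrophages had the largest rises, reactive astrocyte genes were higher too, and Mag and Fa2h, genes of myelin-forming cells, fell. Neither Mag nor Fa2h kept its call in all alternatives but the covariates. Mmp12 rose by 5.93 (SE 0.70, adjusted p = 0.000726), Cybb, the NADPH oxidase subunit of phagocytes, by 4.86, Mpeg1 by 4.36, C3ar1 by 4.33, Tyrobp by 4.33 and Ly86 by 4.27. At 0 weeks Mmp12, Cybb and Mpeg1 averaged below the lower quartile of the arrays, so the sizes of their rises are uncertain. Gfap rose by 2.28 (SE 0.46, adjusted p = 0.0172, with a range of 0.000458 to 0.999 over the alternatives) and Serpina3n by 2.75 (SE 0.35, adjusted p = 0.00121). Gfap missed the threshold without replicate 2 or 3 of the 0-week group (adjusted p = 0.0717 and 0.0516) or replicate 2 or 3 of the 12-week group (0.0678 and 0.0698). Limma called 514 genes, 412 higher and 102 lower, with 355 of them at least 2-fold. With array weights it called 919, 640 higher and 279 lower.

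Of 15 microglial markers, 13 rose at 12 weeks (14 adjusted over the list alone), with a median of 2.99. They included Aif1 (4.25), C1qa (3.79) and Laptm5 (3.70), with Aif1 below the lower quartile of the arrays at 0 weeks. Of 13 genes linked to disease-associated microglia, 5 rose (12 adjusted over the list alone), among them the glycoprotein gene Gpnmb (2.61), the integrin gene Itgax (2.41) and the cystatin gene Cst7 (1.95). These lists had adjusted p = 1.82e-25 and 3.28e-13, and adjusted p = 0.116 and 0.133 with an estimated correlation. Antigen presentation genes rose alongside, with 4 of 13 past the threshold (10 adjusted over the list alone): B2m (2.12), Psmb8 (1.60) and the class II genes H2-Ab1 (1.15) and H2-Eb1 (1.12). Their list had adjusted p = 3.93e-09, and adjusted p = 0.116 with an estimated correlation. Endothelial markers had 4 of 11 members past the threshold (10 adjusted over the list alone), the tight junction gene Cldn5 (1.61), Ly6c1 (1.60), Cdh5 (1.41) and Eng (1.05), with adjusted p = 4.23e-09, and adjusted p = 0.153 with an estimated correlation. None of these 4 genes kept its call in all alternatives but the covariates.

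The pan-reactive astrocyte list had a median of 0.89 at 12 weeks, with Serpina3n, Gfap, the heat shock gene Hspb1 (1.15) and the ceruloplasmin gene Cp (1.02) rising among 13 (9 adjusted over the list alone). Its call (adjusted p = 5.11e-10) was the only list call of this comparison that held with an estimated correlation (adjusted p = 0.0183). Integrated stress response genes rose in 5 of 25 cases (10 adjusted over the list alone), with Asns at 1.93, Nupr1 at 1.70, Atf3 at 1.68 and Ddit3 at 1.18. Their list had adjusted p = 0.000378, and adjusted p = 0.153 with an estimated correlation. Immediate early and dissociation genes rose with these changes in 6 of 19 cases (10 adjusted over the list alone), with a median of 0.60. The rises included Junb (2.38), Zfp36 (1.76), Fosb (1.75) and Egr2 (1.57). Handling can raise such genes, but whether it differed between the groups is not given, so the cause was not tested. Their list had adjusted p = 2.91e-09, and adjusted p = 0.124 with an estimated correlation. Complement gene C4b rose by 1.37, Igf1 by 2.40 and Apoe, the main lipid carrier gene of astrocytes, by 0.73.

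Cholesterol synthesis genes had a median of -0.61 at 12 weeks, with Sqle (-0.88) and Dhcr7 (-0.78) falling among 19 (13 adjusted over the list alone). The homeostatic astrocyte list had a median of -0.57, and Gja1 (-0.92) was its one member past the threshold (7 adjusted over the list alone). These calls had adjusted p = 7.58e-10 and 5.68e-08, and adjusted p = 0.145 and 0.191 with an estimated correlation. Slc1a3 was at 7.30 ± 0.28 (SD, n = 3) against 8.35 ± 0.44 (SD, n = 3), a difference that missed the threshold (adjusted p = 0.0545) but passed it under 6 of 19 alternatives: median centring (0.0448), without the dimmest 30% of genes (0.0481), trend and robust variance (0.0466), array weights (0.0228), only the 6 arrays compared (0.0332) and the ependymal marker mean as a covariate (0.0145, chosen after seeing the data), within a range of 0.0145 to 0.999. Mature oligodendrocyte markers had a median of -0.76, and Mag (-0.93), a myelin adhesion gene, was the 1 of 11 that fell (8 adjusted over the list alone), with adjusted p = 2.07e-06 for the list and adjusted p = 0.191 with an estimated correlation. Among the 10 named falls were Fa2h (-1.48), which makes hydroxylated myelin lipids, Carns1 (-1.57), Itgb4 (-1.56), Gdf10 (-1.55), Ppp1r14a (-1.49), Sez6l2 (-1.48), Rab33a (-1.45), the carbonic anhydrase gene Car14 (-1.43), the hexokinase gene Hk1 (-1.41) and Srcin1 (-1.36). No gene passed with the microglial marker mean as a covariate (limma, 859 genes at an unadjusted p under 0.05), and 8 did with the oligodendrocyte marker mean. With the latter the 514 called genes retained a median of 97.9% of their log2 fold change, 455 of them over 75%, while the SE grew 1.37 times, so most of these calls ended with the larger SE and not with a smaller fold. Ppp1r14a was an exception, at -0.37 (SE 0.27). With the microglial covariate the 514 called genes retained a median of 41.1% of their log2 fold change and the SE grew 2.01 times (median over all genes). The microglial median went from 2.99 to 0.023, a fall that was built in because the covariate is the mean of those same markers. The median of antigen presentation genes went from 0.98 to 0.14, of homeostatic astrocyte genes from -0.57 to 0.021 and of cholesterol synthesis genes from -0.61 to -0.34. For immediate early genes it went from 0.60 to 0.11 and for endothelial genes from 0.93 to 0.85. For integrated stress response genes it went from 0.23 to 0.35 and for pan-reactive genes from 0.89 to 0.95. Atf3 was then at -0.0011 (SE 0.45), Igf1 at 0.16 (SE 0.35), B2m at 0.21 (SE 0.45) and Gja1 at -0.30 (SE 0.43), while Serpina3n was at 3.11 (SE 0.69) and Asns at 1.85 (SE 0.57). The count was 144 or 105 without replicate 1 or 2 of the 0-week group, and 77 or 276 without replicate 2 or 3 of the 12-week group.

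The changes at 3 and 12 weeks correlated across genes with r = 0.70, although genes are not independent replicates. Both comparisons used the same 0-week arrays, and unchanged groups simulated against shared controls gave a mean r of 0.46, with a range of -0.48 to 0.94 over 100 draws. The covariance of the fold changes was 0.116, against a simulated mean of 0.0274 and a highest simulated value of 0.110. The simulation drew, with replacement and random sign, the differences of each array from its group mean. A draw could thus place the same array in several groups, unlike the real comparison, so these ranges are no close guide to the real values. Of the genes higher at 3 weeks, 145 were also higher at 12 weeks, where independent lists would share 6.65, and 34 were lower at both times, where independent lists would share 1.66. No gene was called in opposite directions. Part of this excess may come from the shared 0-week arrays, which are too few to split.

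**Figure D2:**
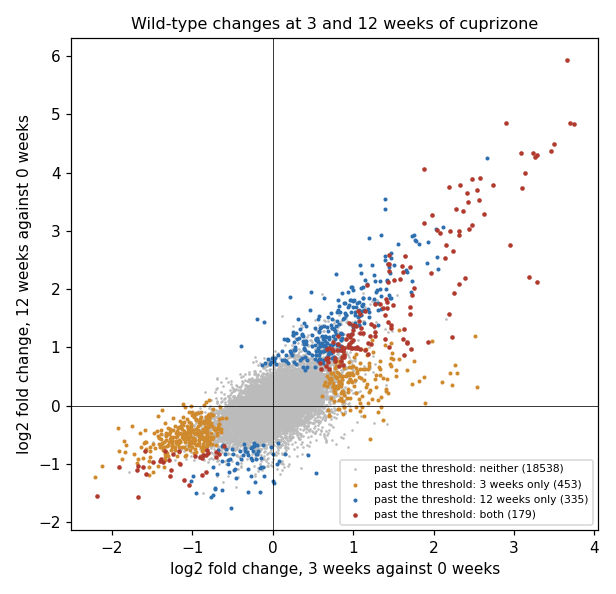
Log2 fold change of each of the 19505 genes at 3 weeks (x axis) and 12 weeks (y axis) of cuprizone against 0 weeks in wild-type cells, coloured by the comparison in which the gene passed the threshold. The 179 genes that passed in both changed the same way.

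The third comparison tested the difference between 12 and 3 weeks directly. Limma called 16 of 19505 genes, 5 higher and 11 lower at 12 weeks. Among the lower ones were Nrsn2 (-2.22), the retrotransposon-derived gene Peg10 (-1.72), Eda2r (-1.63), a TNF receptor family gene, Slc32a1 (-1.62), the vesicular GABA transporter gene, Usp29 (-1.57), Bpifc (-1.84) and Tmem74 (-1.77), which had passed as higher at 3 weeks against 0 weeks and did not pass at 12 weeks against 0 weeks. Eda2r, for example, was at 5.65 ± 0.10 after 3 weeks and 4.02 ± 0.37 after 12 weeks (SD, n = 3 each, adjusted p = 0.0199). Gjb1, the connexin gene of oligodendrocytes (-1.69), Rffl (-1.29) and Prox1 (-1.28) were also lower. Prex2 (1.41), Rpe65 (1.55), the lysosomal pump gene Atp6v0d2 (1.54), Slamf7 (1.47) and Klrb1c (1.43) were higher, the last from a signal below the lower quartile of the arrays in both groups. Bpifc and Tmem74 averaged below that quartile at 12 weeks, and Slamf7 and Atp6v0d2 at 3 weeks. The remaining fall, outside the rule for named genes and picked after its value was seen, was Ppfibp2 (-1.25).

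Of the genes that set 12 weeks apart from 3 weeks, 7 of the 11 lower ones had been called higher at 3 weeks against 0 weeks, and 2 of the 5 higher ones had been called lower, where independent lists would share 0.178 and 0.0813. Both comparisons used the same 3-week arrays, with opposite sign. In unchanged groups simulated with shared arrays no gene was called in both, but the same numbers of genes with the smallest p (11 and 315, or 5 and 317) shared a mean of 4.44 (range 0 to 11 over 100 draws) or 2.33 (range 0 to 5), so part of the overlap may come from the shared 3-week arrays. Neither Gfap (0.31, adjusted p = 0.853) nor Slc1a3 (0.30, adjusted p = 0.730) passed the threshold between the times. Camera called 15 lists (9 without replicate 2 of the 3-week group), with no member of any of them past the threshold over all genes and none held with an estimated correlation. Mature oligodendrocyte markers had a median of -0.74 (adjusted p = 5.11e-06, and adjusted p = 0.439 with an estimated correlation), with 6 of 11 adjusted over the list alone. Neuron markers had a median of -0.35 (adjusted p = 0.00881, and adjusted p = 0.439 with an estimated correlation), with 0 of 10 called by limma over all genes and 2 adjusted over the list alone. Microglial markers had a median of 0.89 (adjusted p = 6.03e-05, and adjusted p = 0.459 with an estimated correlation), with 0 adjusted over the list alone. No gene passed with the microglial or the oligodendrocyte marker mean as a covariate (limma, 1880 and 1031 genes at an unadjusted p under 0.05). The 16 called genes retained a median of 97.2% and 83.8% of their log2 fold change, with 16 and 12 of them over 75%, and the SE grew 1.14 and 1.33 times, so these losses do not tie the calls to either cell type. The count was 9 without the dimmest 30% of genes or with only the 6 arrays compared, 30 with trend and robust variance and 33 with array weights. It was 146, with 92 higher and 54 lower, without replicate 1 of the 3-week group, 4 or 0 without replicate 2 or 3 of that group (limma, 1751 genes at an unadjusted p under 0.05 for the last), and 2 or 1 without replicate 2 or 3 of the 12-week group.

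The fourth comparison asked what GnT-IX deficiency changed after 12 weeks of cuprizone. GnT-IX, encoded by Mgat5b, is a glucosaminyltransferase of the brain that branches O-mannosyl glycans. Mgat5b itself was at 3.70, 4.19 and 4.06 in the 3 deficient arrays and between 5.57 and 6.49 in the 9 wild-type arrays, as their labels have it, though whether the probes lie in the deleted part is not given in the sources used here. It fell by 1.82 (SE 0.21, adjusted p = 0.00159) and was the only gene called lower. The 4 genes called higher were Gm3893 (3.02, SE 0.24, adjusted p = 3.69e-05), the membrane protein gene Emb (2.62, SE 0.29, adjusted p = 0.00159), Fam205a2 (1.81, SE 0.23, adjusted p = 0.00566) and Cd55 (1.59, SE 0.23, adjusted p = 0.0178), which encodes a regulator of complement. Limma thus called 5 of 19505 genes.

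Mgat5b did not change with cuprizone beyond the spread in wild-type cells (0.36 at 3 weeks, adjusted p = 0.426, and 0.13 at 12 weeks, adjusted p = 0.845). Gfap differed by -0.45 between the genotypes (adjusted p = 0.860), with 6.86 to 9.26 in the deficient arrays, and Slc1a3 by -0.03 (adjusted p = 0.986). Gm3893, Fam205a2 and Cd55 belong to families with near-identical copies, so their values are uncertain. With the mean over its probe sets in place of the brightest, Fam205a2 differed by 0.92 (adjusted p = 0.399). Cd55 missed the threshold without replicate 1 (adjusted p = 0.0808) or replicate 3 (0.109) of the wild-type 12-week group or replicate 2 of the deficient group (0.179), and Fam205a2 without replicate 3 of the wild-type group (0.0719). Over all alternatives the adjusted p ranged from 0.0104 to 0.812 for Cd55 and from 0.00134 to 0.763 for Fam205a2. The remaining genes with the smallest p were Ecrg4 (2.54, adjusted p = 0.0707), Slc13a4 (2.42), Calml4 (1.98), Wfikkn2 (1.65) and Igfbp2 (1.53), given as values and not as calls. Across the deficient arrays Ecrg4 (8.58, 8.17 and 6.73), Wfikkn2 and Igfbp2 ranked with the choroid plexus mean, while Slc13a4 and Calml4 did not. Whether RNA of that tissue raised any of them was not tested.

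**Figure D3:**
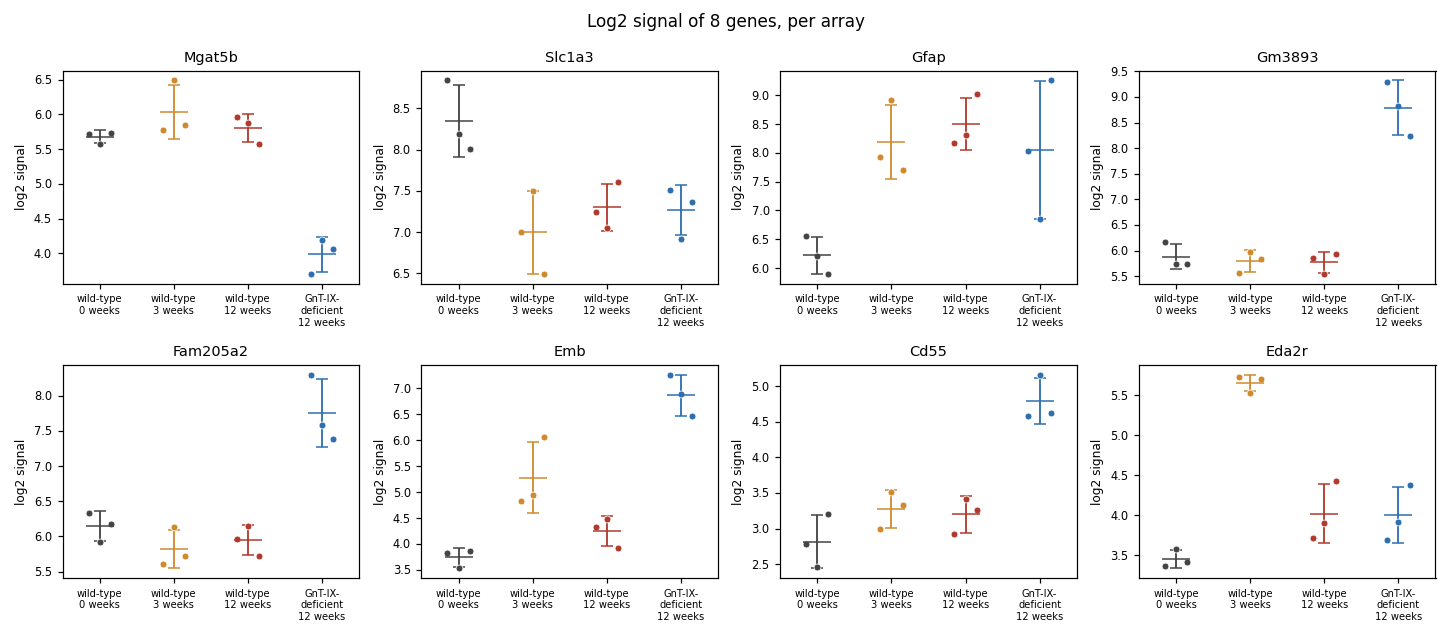
Log2 signal of 8 genes (y axis) in each array (points) by group (x axis), with the group mean and SD as a bar. Mgat5b was at 3.70 to 4.19 in the GnT-IX-deficient arrays, and Gm3893, Fam205a2, Emb and Cd55 were higher there than in all wild-type arrays.

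Camera called 16 lists between the genotypes, 5 higher and 11 lower (10 lists without replicate 2 of the wild-type 12-week group), and none held with an estimated correlation. Choroid plexus markers had a median of 2.53 and ependymal markers of 1.04, with 0 members past the threshold over all genes and 4 of 5 and 7 of 9 adjusted over the lists alone. Ttr, the transthyretin gene of the choroid plexus, chosen after its values were seen, was at 12.47, 12.09 and 9.56 in the deficient arrays, against 7.40, 9.92 and 4.99 in the wild-type arrays at 12 weeks. These lists had adjusted p = 4.62e-07 and 3.22e-11, and adjusted p = 0.311 for each with an estimated correlation. Microglial markers had a median of -0.57, disease-associated microglia genes of -0.42 and pan-reactive astrocyte genes of -0.30, with no member past the threshold (adjusted p = 0.00129, 0.00129 and 0.0225, and adjusted p = 0.500, 0.500 and 0.311 with an estimated correlation). Immediate early and dissociation genes had a median of -0.25, with 0 of 19 called by limma (adjusted p = 0.00479, and adjusted p = 0.465 with an estimated correlation). Cytochrome c oxidase and metal handling genes had a median of 0.25 (adjusted p = 0.00129, and adjusted p = 0.311 with an estimated correlation). Of the O-mannosyl glycan genes, Mgat5b alone passed among 16, with a median of -0.15 for the list (adjusted p = 0.0102, and adjusted p = 0.311 with an estimated correlation). Mgat5b is the targeted gene, so its fall enters this list test, and the other members were not tested apart from it.

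The genes that changed at 3 weeks in wild-type cells were also followed across the genotypes. The 12-week arrays entered the spread by which these genes were called, but not the means compared. The 315 genes higher at 3 weeks had a median difference of 0.0033 between deficient and wild-type cells at 12 weeks (camera, adjusted p = 0.994), which passed the threshold in opposite directions without replicate 1 (0.078) and without replicate 3 (-0.12) of the deficient group. Limma called 1 of these genes higher in deficient cells. Emb lay higher in wild-type cells at 3 weeks (4.83, 4.94 and 6.06) than at 0 weeks (3.83, 3.53 and 3.86). The 317 genes lower at 3 weeks had a median of -0.18, with 250 of them below 0 (camera, adjusted p = 3.23e-09), and adjusted p = 0.487 with an estimated correlation. That median was -0.29 without replicate 1 and -0.10 without replicate 3 of the deficient group, and -0.29 without replicate 2 and -0.073 without replicate 3 of the wild-type 12-week group. With the choroid plexus marker mean as a covariate, an alternative chosen after seeing the data, 1 gene passed between the genotypes, Gm3893 (2.68, SE 0.32). The differences of the others stayed at 1.56 (SE 0.33, of 1.59) for Cd55, -1.64 (SE 0.29, of -1.82) for Mgat5b, 1.48 (SE 0.31, of 1.81) for Fam205a2 and 1.90 (SE 0.31, of 2.62) for Emb, while the SE grew 1.41 times (median over all genes). With the ependymal marker mean as a covariate, likewise chosen after seeing the data, 2 genes passed, Gm3893 (3.39, SE 0.32) and Fam205a2 (2.30, SE 0.29). Emb was then at 2.52 (SE 0.42), Mgat5b at -1.90 (SE 0.30) and Cd55 at 1.48 (SE 0.33), while the SE grew 1.43 times. The count was 8 over every transcript cluster, 3 without replicate 3 of the wild-type 12-week group, 9 without replicate 1 of the deficient group and 49 without replicate 3 of the deficient group, which had the lowest choroid plexus mean of the 3.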

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

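The tests of microglial RNA, of a lower astrocyte share, of carry-over for choroid plexus and ependymal genes, of slopes without Ttr, of a genotype effect on choroid plexus genes, of DNA flanking Mgat5b and of a segment difference were chosen after the results were seen. The slopes on the choroid plexus mean with Ttr were taken for the genes called higher in deficient arrays, so that test too followed those calls.

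The effects of 3 and 12 weeks of cuprizone on wild-type cells differed, by the limma test of the difference itself (12 minus 3 weeks, log2), for 16 genes. They were lower at 12 weeks for Nrsn2 (-2.22), Bpifc (-1.84), Tmem74 (-1.77), Peg10 (-1.72), Gjb1 (-1.69), Eda2r (-1.63), Slc32a1 (-1.62), Usp29 (-1.57), Rffl (-1.29), Prox1 (-1.28) and Ppfibp2 (-1.25). They were higher for Prex2 (1.41), Klrb1c (1.43), Slamf7 (1.47), Atp6v0d2 (1.54) and Rpe65 (1.55). Without replicate 3 of the 3-week group limma called 0 genes here, without replicates 1 and 2 of that group 146 (92 higher, 54 lower) and 4, and without replicates 2 and 3 of the 12-week group 2 and 1. At an unadjusted p under 0.05 there were 2222 genes with all arrays.

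Transcript clusters that are unnamed here, and so stood outside the gene tests, also differed. Of 2634 such clusters, 32 were higher and 25 lower at 3 weeks, 68 were higher and 7 lower at 12 weeks, and 3 were higher and 0 lower in GnT-IX-deficient cells, where limma gave 162 at an unadjusted p under 0.05 in either direction.

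For each comparison, 1 of the 10 splits of its 6 arrays, the real one, gave as many genes as were counted (632, 514, 16 and 5), and the highest of the other splits gave 0 by limma, with 1951, 1947, 1888 and 1411 genes at an unadjusted p under 0.05, against 3142, 2938, 2222 and 1363 for the real splits. Between the genotypes another split thus gave more genes at an unadjusted p than the real one. With 10 splits no share under 0.05 can be reached.

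After cuprizone, 10 of 15 microglial genes rose and 8 of 18 homeostatic astrocyte genes fell at 3 weeks (adjusted p = 0.153 for each list with an estimated correlation), and 13 and 1 did at 12 weeks (adjusted p = 0.116 and 0.191 with an estimated correlation). A lower astrocyte share alone would raise the markers of all other cells alike. The microglial median exceeded the mature oligodendrocyte median by 3.75 at 12 weeks, against a member SD of 0.779. Cuprizone kills oligodendrocytes, so this gap alone cannot decide the question. From 0 to 12 weeks the microglial mean went from 5.39 to 8.32. Means of other cells rose less: endothelial from 5.75 to 6.74, pericyte and smooth muscle from 7.58 to 7.89 and neuron from 6.35 to 6.40. An amount of microglial RNA that differs between arrays is consistent with the markers varying together within groups: in 57 of 60 pairs of marker and group the array with the highest mean of the other markers was highest for the marker. C1qa was the brightest of the 15 at 0 weeks, at 6.66, and none of the 15 is on another list. At 0 weeks 8 lay above the array median, about the share that genes at large would show, so this count does not show microglial RNA then. The anti-GLAST selection is meant to remove such cells. Mature oligodendrocyte markers still averaged 9.62 at 0 weeks after it, and how well it removed microglia was not tested here. Whether there were more microglia, more RNA per microglial cell, or microglial genes made in astrocytes stays open, as does a change within astrocytes beside it.

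In the GnT-IX-deficient arrays, choroid plexus and ependymal genes were higher on average than in wild-type arrays at 12 weeks, but not in every array. No member passed the threshold over all genes, and neither list call held with an estimated correlation. Carry-over of ventricle lining at dissection is consistent with 22 of 27 pairs of ependymal marker and wild-type group, in which the array with the highest mean of the other markers was highest for the marker, while the same test gave 12 of 15 pairs for choroid plexus but 7 of 12 without Ttr, so carry-over of that tissue stays open. The lists part in the deficient arrays: replicate 1 had the highest choroid plexus mean (9.66) and the lowest ependymal mean (7.13, under a wild-type maximum of 7.23), and replicate 3 the lowest choroid plexus mean (6.33) with an ependymal mean of 7.84, so carry-over would need different amounts of each tissue. Kcnj13, at 7.34, was the brightest of the 5 choroid plexus markers at 0 weeks, and none is on another list. There 3 lay above the array median, about the share that genes at large would show. Carry-over would also have to pass the anti-GLAST selection, and whether that step removes such cells was not tested here. An effect of the genotype stays open too: 2 of the 3 deficient arrays lay above all wild-type arrays in choroid plexus mean, and no deficient array without cuprizone was analysed here.

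Gm3893, Emb, Fam205a2 and Cd55 were higher in GnT-IX-deficient arrays. DNA flanking the targeted gene would place them near Mgat5b, but 0 of the 4 lie on its chromosome (GRCm38.p6), and of 10 measured neighbours of Mgat5b none was called by limma (-0.40 to 0.23). The slope on the choroid plexus mean within wild-type arrays gave at most -5.64% of the difference for Gm3893 and Fam205a2, and -20.0% without Ttr in that mean. That slope covers means of 4.80 to 6.81 only, so it cannot show what a higher mean would do. Across the deficient arrays both genes ranked with the choroid plexus mean. Replicate 3, with a mean of 6.33 inside the wild-type range, still had Gm3893 at 8.24 and Fam205a2 at 7.38, above all wild-type arrays. This argues against choroid plexus RNA as the only source for this pair, while a part from it stays open. For Emb the slope gave 37.8% (0.99 ± 0.40, SE, of 2.62), and 74.7% without Ttr. For Cd55 it gave -0.42% and 8.51%, from a wild-type signal below the lower quartile of the arrays. Across the deficient arrays Emb (7.25, 6.89 and 6.46) ranked with the choroid plexus mean, while Cd55 (4.58, 5.16 and 4.62) did not. Both lay above all wild-type arrays in replicate 3. That rests on replicate 3 alone, and Cd55 was dim in wild-type arrays, so choroid plexus RNA stays open for both. A copy number or strain difference in the segment that holds Gm3893 and Fam205a2 stays open too: 0 of the 4 measured genes between them passed, with differences of 0.16 to 0.58, and an effect of the genotype itself was not tested apart from these.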

How the results depend on the processing

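The choroid plexus and ependymal covariates were chosen after seeing the data. Signal over background was not measured here, so dim genes are the least certain. For 3 against 0 weeks, 632 genes became 5 with the microglial covariate and 367 at a minimum of 2-fold, and 192 to 643 with one array left out. For 12 against 0 weeks, 514 became 919 with array weights, 0 with the microglial covariate (limma, 859 at an unadjusted p under 0.05) and 8 with the oligodendrocyte covariate, and 77 to 504 with one array left out. For 12 against 3 weeks, 16 became 9 without the dimmest 30% of genes, 30 with trend and robust variance, 33 with array weights, 9 with only the 6 arrays compared, 0 with the microglial and 0 with the oligodendrocyte covariate (limma, 1880 and 1031 at an unadjusted p under 0.05), and 0 to 146 with one array left out. Between the genotypes, 5 became 8 over every transcript cluster, 1 with the choroid plexus and 2 with the ependymal covariate, and 3 to 49 with one array left out. The arrays behind these ranges were replicate 1 of the 0-week group (192) and 2 of the 3-week group (643), replicates 2 (77) and 1 (504) of the 12-week group, replicates 3 (0) and 1 (146) of the 3-week group, and replicate 3 of the wild-type (3) and of the deficient (49) 12-week group. With the microglial covariate a median of 81.3% (3 weeks) and 41.1% (12 weeks) of the fold of the called genes was left, and the SE grew 1.58 and 2.01 times. With the oligodendrocyte covariate 97.9% was left at 12 weeks with an SE 1.37 times larger, and for 12 against 3 weeks 97.2% (microglial) and 83.8% (oligodendrocyte) were left with an SE 1.14 and 1.33 times larger, so these calls ended mostly with the SE; the cause of the other changes was not tested. Called lists numbered 17, 16, 15 and 16 in the 4 comparisons, became 0, 1, 0 and 0 with an estimated correlation and 9, 13, 0 and 0 by fry, and with one array left out 9 (without replicate 2 of the 3-week group) to 14 for 12 against 3 weeks and 10 (without replicate 2 of the wild-type 12-week group) to 19 between the genotypes. Across the genotypes, the genes lower at 3 weeks (median -0.18, which the choice of set test cannot move) did not pass with an estimated correlation or by fry and had medians of -0.29 (without replicate 1 of the deficient group) to -0.073 (without replicate 3 of the wild-type group) with one array left out, all past the threshold. The genes higher at 3 weeks had medians from -0.12 (without replicate 3 of the deficient group) to 0.078 (without replicate 1 of that group), both past the threshold, in opposite directions. With the microglial covariate at 12 weeks the sign turned for Aif1 (-0.56), Atf3 (-0.0011), Cst7 (-0.69), Ifit1 (-0.11), Itgax (-0.33), Psmb8 (-0.13), Tgfb1 (-0.44), Usp18 (-0.18) and Zfp36 (-0.11), but not for Serpina3n (3.11) or Asns (1.85). Aif1 is itself part of that marker mean, so its sign there carries no separate weight. Of the named genes called, 37 of 67, 21 of 64, 0 of 15 and 3 of 5 kept their call in all alternatives but the covariates. With the replicate block the counts were 543, 442, 15 and 5; 6 of 18 pairs with the same number correlated above 0.1 and 4 of 12 arrays correlated best with their own number, so the numbers were not taken to pair the arrays.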

Other observations

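The 4 gene lists of this part, their tests, and the genes named from them were chosen after the results were seen.

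Targets of p53, the DNA damage transcription factor, rose at 3 weeks in 6 of 25 measured cases and none fell, with a median of 0.29. Besides Cdkn1a (3.28) these were Eda2r (2.20), Phlda3 (1.88), Ccng1 (1.46), Plk2 (0.79) and Mdm2 (0.75), which encodes the ligase that degrades p53. Camera gave adjusted p = 2.14e-06, and adjusted p = 0.0088 with an estimated correlation. At 12 weeks 3 of the 25 rose, Cdkn1a (2.13), the immediate early gene Btg2 (1.23) and Cd80 (1.10), a gene of myeloid cells, while Eda2r, Phlda3, Ccng1, Plk2 and Mdm2 did not pass. The median was 0.21, adjusted p = 0.000364, and adjusted p = 0.0238 with an estimated correlation. Cdkn1a and Eda2r had drawn attention to this list, so it is not independent of them. The 0-week arrays had Cdkn1a at 9.02, 9.29 and 6.54, so replicate 3 of that group enlarged its rise at both times. Microglial markers (medians of 2.28 at 3 weeks and 2.99 at 12 weeks) and immediate early genes were higher in the same arrays. Eda2r was among the genes that still passed at 3 weeks with the microglial covariate.

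Cytosolic ribosomal protein genes rose in 24 of 62 cases at 3 weeks (median 0.68) and 41 of 62 at 12 weeks (median 0.81), and none fell, with adjusted p = 0.108 and 0.0749 with an estimated correlation. Microglial marker means were higher in the same arrays. Of 16 cytosolic aminoacyl-tRNA synthetase genes, Eprs, Yars, Gars, Mars1 and Nars rose at 3 weeks (median 0.50, adjusted p = 5.97e-07, and adjusted p = 0.0749 with an estimated correlation). At 12 weeks limma called 0 of the 16 (9 at an unadjusted p under 0.05), with a median of 0.25, adjusted p = 0.0213, and adjusted p = 0.348 with an estimated correlation. NADH dehydrogenase subunit genes had a median of 0.29 in GnT-IX-deficient against wild-type cells, with 0 of 35 called by limma over all genes (9 at an unadjusted p under 0.05), adjusted p = 1.15e-13, and adjusted p = 0.187 with an estimated correlation. Choroid plexus (median 2.53) and ependymal (1.04) markers also leaned higher between these groups, with no member past the threshold over all genes and neither list call held with an estimated correlation. They were not higher in every array: replicate 3 of the deficient group had a choroid plexus mean of 6.33, under 6.41 in a wild-type array at 12 weeks.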
